A study of Arabidopsis thaliana with 6 samples.

How the data were processed

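Transcript levels in shoots of 2-week-old Arabidopsis thaliana seedlings were measured on 6 Affymetrix ATH1 arrays, each hybridised with biotin-labelled RNA of a single sample. The seedlings carried an estradiol-inducible MYB112 construct (MYB112-IOE, line 1, Col-0 background). Per the labels' protocols, plants grew on agar at 22 °C in continuous light of 100 µmol m-2 s-1, were moved to shaken liquid medium, and received 10 µM β-estradiol 16 h later. Groups were taken from the labels: estradiol at 3 h (n = 1), DMSO at 3 h (n = 1), estradiol at 5 h (n = 2) and DMSO at 5 h (n = 2). The labels number the samples as biological replicates but do not say whether each came from its own flask, so p-values measure the spread between these samples only. Estradiol-treated plants without the construct were not analysed here.

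The authors deposited 1 log2 value per probe set and array. GCRMA and RMA are named in the submitters' processing notes, without versions or roles, and the log base is not given in the sources used here. Base 2 was taken from the range of the values, 2.1 to 15.35, and all fold values rest on that reading. No centring by gene was seen. Signal over background cannot be read from these values, and the number of arrays limits the precision. The median of the array values was 5.82 and 5.83 in the estradiol and DMSO arrays at 3 h, 5.46 and 5.40 in replicate 1 at 5 h, and 5.04 and 5.12 in replicate 2 at 5 h. Each pair of the same time and number had a lowest value of its own, 2.1, 2.14 or 2.16, at which many probe sets sat. The Pearson correlation over probe sets was 0.998, 0.996 and 0.994 within pairs and 0.957 to 0.968 between arrays of different pairs. The 3 pairs were therefore treated as having been normalized separately, although no source used here states it. For this reason the planned test of 5 h against 3 h was not run, since it would have compared levels between separately normalized tables; differences of estradiol and DMSO arrays within pairs were used instead. The planned fits of estradiol against DMSO without a pair term were kept, and their residual spread includes the differences between the separately processed pairs.

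The table held 22810 probe sets, of which 64 were control probe sets and 22746 were kept. Names came from the platform annotation that pairs probe sets with genes, updated through gene numbers to the RefSeq annotation of the TAIR10.1 assembly. Of the probe sets, 13513 had 1 gene (13436 matched to the newer table), 503 had several genes and were not named, and 8730 were not listed there and are unnamed here. Probe sets without a named gene are described by their values. The annotation used here named MYB112 on 0 probe sets, so the planned report of its level on each array could not be made and no probe set is called MYB112. The build behind the array annotation is not given in the sources used here, so no coordinates are printed.

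Tests were made in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Probe sets entered a fit when at least 2 of its arrays reached the 40th percentile of the table, 3.56 on the log2 scale. This kept 14078 probe sets for the 5 h fit of 4 arrays (2 residual degrees of freedom) and 14520 for the fit of all 6 arrays with time as a covariate (3 residual degrees of freedom). The difference of the estradiol effect between 5 h and 3 h was an interaction contrast in a 4-group fit (2 residual degrees of freedom). The 3 h pair had 1 array per treatment and was described without a test, by probe sets at least 2-fold apart. Probe sets at least 2-fold apart in the same direction in all 3 pairs were counted as a further description. Gene lists were tested with camera at an inter-gene correlation of 0.01 and with an estimated correlation, using for each gene its probe set of highest mean, and at 3 h were ranked among 10000 random lists matched on mean level. Of 30 lists with 326 entries fixed before the data were examined, the annotation named 46 entries, and 4 lists had at least 3 members above the filter and were tested. The fixed lists covered flavonoid, anthocyanin, phenylpropanoid, hormone, stress, glucosinolate, nutrient, clock and photosynthesis genes, markers of other organs and cell types, and reference genes. Another 31 lists were added after seeing the data, namely 29 families sharing a symbol prefix (at least 5 members), chloroplast-encoded genes, and 51 core low-oxygen response genes taken from general knowledge.

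Whether replicate numbers pair the samples was checked before calls were compared. The deviations of same-numbered estradiol and DMSO arrays from their treatment means correlated at 0.943, 0.923 and 0.906 over probe sets in the 3 pairs. These means cover 3 h and 5 h, so the deviations also hold any difference of time. Within 5 h, the difference of replicate 1 and replicate 2 correlated at 0.901 between estradiol and DMSO. Same-numbered arrays therefore share a deviation, which a pair term can take up. Joint processing of each pair could give this by itself, so the check cannot show that the samples were paired biologically. Blocked fits with the pair as a term had 1 residual degree of freedom at 5 h and 2 over both times. The scripts were tested on simulated data with 50 probe sets for each size of change. At 5 h, over 14147 probe sets, 2% of simulated log2 changes of 2 and 68% of changes of 8 were called, and 8% and 94% with the pair as a block. Over both times, over 14571 probe sets, 24% of log2 changes of 1 and 92% of changes of 3 were called, with 0 false calls. With the pair as a block these shares were 48% and 92%, with 4 false calls. All sizes of change were planted in the same simulated data, which makes the Benjamini-Hochberg adjustment more lenient than in data with few changes. The shares therefore overstate what could be called if few probe sets changed.

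PDC2, AT3G27220, PDF1.2b, PDF1.4, XTH33 and UGT72E1 were chosen after their values were seen. The other named genes followed a rule fixed before the data were examined. It took MYB112 and its subgroup 20 relatives, of which the annotation named 0. At 5 h it took, among 1-gene probe sets past the threshold that moved the same way in each pair, the 15 largest rises and the 10 largest falls. Over both times it took the 10 largest rises and 8 largest falls past the threshold. Directions with fewer were filled, to 10 at 5 h and to 5 over both times, with the smallest unadjusted p among 1-gene probe sets at least 1 apart on the log2 scale and in the same direction in the pairs. At 3 h it took the 8 largest rises and 5 largest falls among 1-gene probe sets. It further took all probe sets at least 2-fold apart in all 3 pairs (up to 30 per direction, otherwise 15) and up to 5 per direction for the interaction. From each list it took up to 4 members past the threshold or, where none passed, up to 3 measured members with the largest difference. It also took the reference genes and the array's actin and GAPDH controls, and planned 8 genes per direction for the time comparison, which was not run. Alternatives covered the filter, the eBayes prior, quantile normalization, centring on the median, the pair as a block, thresholds, and leaving out each array or pair. The control probe sets were left out because their levels ranked differently between pairs (rank correlations across the 64 of 0.752, 0.350 and 0.434, where those of the other probe sets were at least 0.956), so the planned check on actin and GAPDH controls was not made. Python 3.11.15 with pandas 2.3.3 prepared the table, and figures were drawn with matplotlib 3.10.9.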

Results

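Transcript levels were compared between estradiol-treated and DMSO-treated shoots of seedlings in which β-estradiol switches on MYB112, an R2R3-MYB transcription factor. At 3 h after treatment there was 1 array per treatment, and at 5 h there were 2 per treatment (6 arrays in all). The series asks which genes respond early to MYB112 and are potential direct targets. The number of arrays limits the precision of all values below, which are differences between estradiol and DMSO arrays on the log2 scale unless stated otherwise. The level of MYB112 itself was not analysed here, because no probe set carried its name in the annotation used.

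At 5 h, the comparison with 2 arrays per treatment, a single probe set, for which no gene is named here, rose by 10.10 (SE 0.30, n = 2 arrays per treatment, limma adjusted p = 0.0263), a fold change of 1098. Its estradiol values were 12.87 and 13.30, and its DMSO values of 2.70 and 3.27 lay near the lowest value of the arrays, so the fold depends on that floor. Which gene it detects is not given in the sources used here, and it is called the induced probe set in what follows. Estradiol switches on MYB112 in these seedlings. Whether the induced probe set detects MYB112 itself or a gene that responds to the treatment therefore cannot be told here. UGT85A2, a UDP-glucosyltransferase, was 1.88 higher (SE 0.14), with differences of 1.88 and 1.87 in the 2 pairs, and did not pass (adjusted p = 0.837). HAT2, an auxin-inducible homeodomain-leucine zipper gene, was at −1.25 (SE 0.22), and AT3G10040 (HRA1, a regulator of the low-oxygen response) was at −2.22 (SE 0.39), neither passing (adjusted p = 1 for each).

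The other genes named at 5 h did not pass either (adjusted p = 1 for each). Among those with higher values, AT5G38320 differed by 4.0, from DMSO values near the floor, AT4G38950 by 3.81 and AT3G18250 by 3.32. AT5G19875 differed by 2.25, AT5G52810 by 1.72 and AT4G24380 by 1.47. Differences were 1.13 for AT2G29340, 1.12 for AT4G36640 and 1.05 for AT1G74640. Among those with lower values, AT4G24110 was at −2.36, AT5G42200 at −1.63, AT1G21050 at −1.49 and AT5G03230 at −1.39. PGM was at −1.23, AT1G23390 at −1.11, AT5G12050 at −1.10 and AT4G27450 at −1.03. Of 14078 probe sets tested with limma, 1 rose and 0 fell, and 162 had an unadjusted p under 0.05. That is less than the share of 0.05 expected without any effect. The residual spread of this fit includes the differences between pairs, so the lack of calls is no evidence that other genes did not change. With the pair as a block, limma called 0 probe sets (smallest adjusted p = 0.114), with 1167 at an unadjusted p under 0.05, more than a share of 0.05. The call of the induced probe set was also lost without either estradiol array of 5 h (0 calls each).

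Over both times, which asks for an effect shared by 3 h and 5 h, the induced probe set rose by 9.47 (SE 0.45, n = 3 arrays per treatment, limma adjusted p = 0.048). It was higher with estradiol in 3 of 3 pairs, by 8.21 at 3 h and by 10.17 and 10.03 at 5 h. No other probe set passed. AT3G10040 was at −2.36 (SE 0.26), the named gene with the smallest unadjusted p in the fit without the block (2.18e-04), with an adjusted p of 1. With the pair as a block its unadjusted p was 0.00116, and AT4G10270, at −1.71, had a smaller one (4.56e-04), each with an adjusted p of 0.50. The adjusted p was also 1 for AT5G48430 at 2.79, AT3G22060 at 1.99, AT1G51820 at 1.67, UGT85A2 at 1.41 and AT5G52810 at 1.32. It was 1 as well for AT5G42200 at −1.82, AT4G27450 at −1.26, AT1G21050 at −1.24 and HAT2 at −1.04. Of 14520 probe sets tested with limma, 1 rose and 0 fell, and 276 had an unadjusted p under 0.05. As at 5 h, that is less than a share of 0.05, and the blocked fit exceeded that share. With the pair as a block the induced probe set had an adjusted p of 0.50 and limma called 0 (smallest adjusted p = 0.119), with 1415 at an unadjusted p under 0.05, and without any single 5 h array the call was lost as well.

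At 3 h, the earlier time after estradiol was added, AT3G22060 was 2.69 higher with estradiol, AT1G30700 2.66, AT1G51820 1.99 and AT5G48430 1.95 higher. Differences of 1.43, 1.32, 1.3 and 1.2 were measured for AT1G74010, AT4G19430, AT2G40435 and AT2G15830. Lower values were measured for AT1G33055 (−2.74), AT3G10040 (−2.64), AT2G17850 (−2.52), AT5G10040 (−2.43) and AT5G66985 (−2.42). Several of these differences were smaller, near 0 or of opposite sign in a 5 h pair. In replicates 1 and 2 of 5 h, AT1G30700 was at 1.44 and 0.10, AT1G74010 at 1.47 and −0.37, AT4G19430 at 0.19 and 0.12, AT2G40435 at 0.53 and 0.43, and AT2G15830 at −0.39 and 1.32. AT2G17850 was at 0.00 and −1.82 there, and AT5G10040 at −0.06 and −1.23. Of the 14520 probe sets, 31 were at least 2-fold higher and 67 at least 2-fold lower. With 1 array per treatment these differences have no replicate error and were not tested.

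Probe sets that differed at least 2-fold in the same direction in all 3 pairs numbered 6 higher and 12 lower. AT5G48430 differed by 2.79 (SD 1.53, n = 3 pairs) and AT3G22060 by 1.99 (SD 0.67, n = 3 pairs). The induced probe set was among the 6, and the other 3 without a named gene differed on average by 2.04, 1.94 and 1.18. The 6 lower probe sets with a named gene had mean differences of −2.36 for AT3G10040 (SD 0.54, n = 3 pairs), −2.16 for AT1G33055, −2.12 for AT4G24110, −1.82 for AT5G42200, −1.71 for AT4G10270 and −1.70 for AT5G66985. The 6 without a named gene had mean differences of −2.47, −2.38, −2.34, −2.30, −2.12 and −1.76. Independent lists of the size found in each pair would share 0.0034 higher and 0.0081 lower probe sets, and 0 probe sets were 2-fold apart in all pairs with mixed signs. That expectation takes every probe set as equally likely to differ. Probe sets that vary more than others would recur in all pairs without any effect of estradiol, so the excess is no measure of one. At 1.5-fold, 12 probe sets were apart in all pairs with mixed signs, beside 17 higher and 23 lower. Apart from the induced probe set, none of the 6 higher and 12 lower probe sets passed a test over all probe sets.

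**Figure D1:**
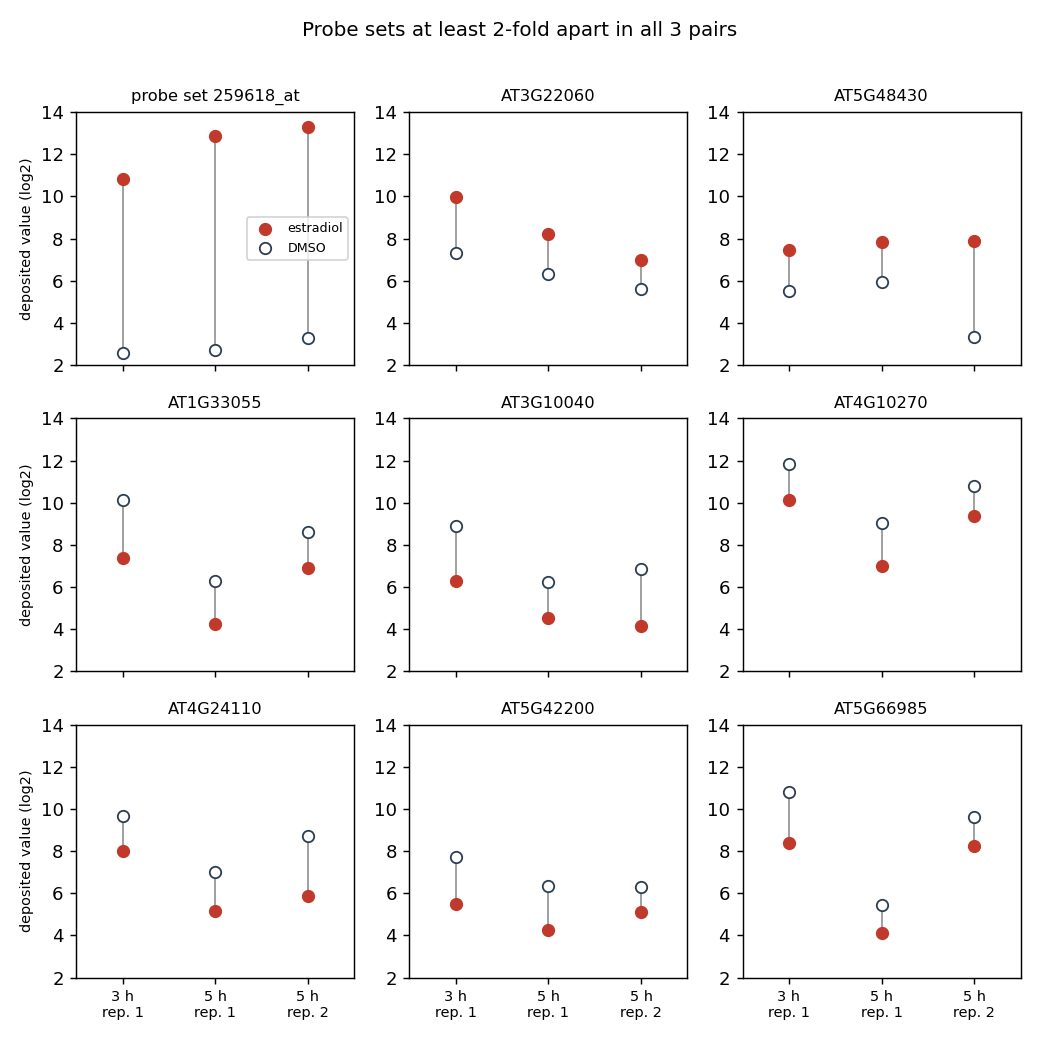
Deposited log2 values of the induced probe set (top left) and of the 8 named genes at least 2-fold apart in all 3 pairs, for each estradiol array (filled) and its DMSO array (open), joined by a line. The values of the induced probe set were 10.80, 12.87 and 13.30 with estradiol and 2.59, 2.70 and 3.27 with DMSO.

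A list of 51 core low-oxygen response genes, known to be induced when oxygen is short, was drawn up after the values were seen, with knowledge of the genes that were lower, so the p-values given for it are no independent evidence. Of its 25 members above the filter, 24 were lower and 0 higher over both times, with a median of −1.05 (camera adjusted p = 6.52e-17 over 31 added lists, 2.22e-12 with the pair as a block). The call was lost with an estimated correlation between genes (adjusted p = 0.992). At 5 h the median was −0.79, with 24 lower and 1 higher (adjusted p = 2.48e-09, and 0.933 with an estimated correlation). In the 3 h pair all 25 were lower, with a median of −1.64. In replicate 1 of 5 h the median was −0.56, with 17 lower, 5 higher and 3 equal, and in replicate 2 it was −1.10, with 23 lower and 2 higher. Members adjusted over the list alone numbered 3 past the threshold over both times and 0 at 5 h, and over all probe sets 0 passed. PDC2, a pyruvate decarboxylase of fermentation, was at −0.36, −0.60 and −0.81 in the 3 pairs, and AT3G27220 at −2.28, −0.56 and −1.82. These members were picked after their values were seen.

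**Figure D2:**
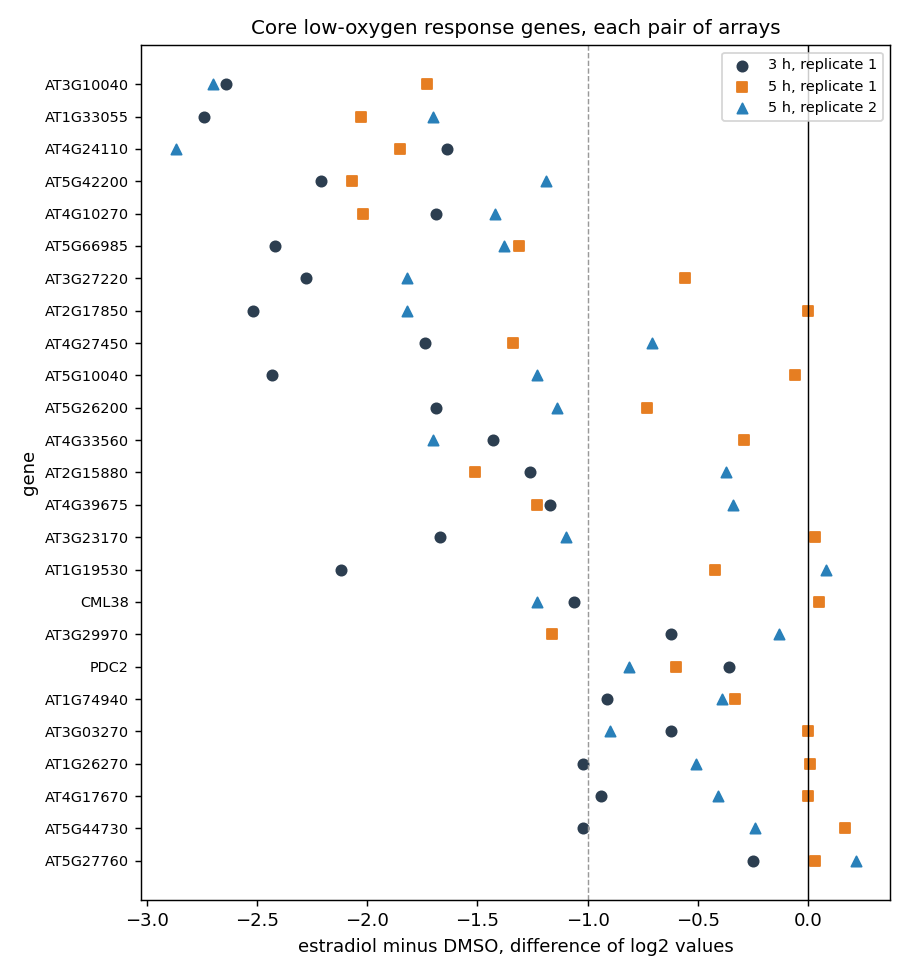
Estradiol minus DMSO difference of log2 values in each of the 3 pairs for the 25 measured core low-oxygen response genes, with the dashed line at −1 and the solid line at 0. All 25 points of the 3 h pair lie below 0.

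Among the lists fixed beforehand, the late anthocyanin enzymes had 4 named members, all under the filter: DFR, AT4G14090, UF3GT and AT5MAT had values of 2.1 to 2.82 in all arrays. Of the early flavonoid and flavonol enzymes, 4 members were tested over both times, 3 lower and 1 higher, with a median of −0.09 (camera adjusted p = 0.807). In the 3 pairs CHIL was at −0.13, −0.01 and −0.23, UGT78D2 at −0.29, 0.34 and −0.36, and AT1G06000 at −0.12, 0.30 and −0.39. The touch and rapid wound genes had a median of −0.15 (adjusted p = 0.807), with CML38 at −1.06, 0.05 and −1.23, WRKY53 at 0.17, 0.55 and 0.35, and STZ at −0.34, 0.25 and −0.37. The xenobiotic and detoxification genes had a median of 0.12 (adjusted p = 0.807), with GSTU25 at −1.55, 3.22 and −0.16, UGT73B4 at −1.13, 1.51 and 0.07, and AT2G21640 at −0.30, 0.15 and −0.45. At 3 h the xenobiotic median was −0.76, at percentile 0.02 of 10000 random lists. The touch median there was −0.34 (percentile 0.95), the early flavonoid median −0.13 (percentile 18) and the reference median 0.00 (percentile 64.1). These percentiles rest on 1 array per treatment and measure spread over genes, not between replicates. In the 5 h pairs the xenobiotic median was 1.08, with 4 of 4 members higher, and −0.07, the touch median 0.25 and −0.37, and the early flavonoid median 0.18 and −0.30. At 5 h camera called 0 of the 3 lists tested, with medians of −0.03 for early flavonoid genes and −0.06 for touch genes (adjusted p = 0.995 each), the former at 0.01 after quantile normalization. In both comparisons limma called 0 members of these lists, over all probe sets and adjusted over the list alone, and without the block 0 had an unadjusted p under 0.05. With the pair as a block, WRKY53 had an unadjusted p of 0.0379 over both times (adjusted p = 0.506).

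Lists with fewer than 3 members above the filter were not tested as lists, and the differences in the 3 pairs were as follows. HCT of phenylpropanoid synthesis was at −0.20, −0.36 and −0.28. The cold and abscisic acid genes COR15A and LTI30 were at −0.05, −0.07 and −0.78 and at −0.21, 0.13 and −0.68. PDF1.2, a plant defensin of the ethylene list, was at 0.72, −1.31 and −0.93. The auxin-conjugating enzyme genes WES1 and GH3.3 were at −0.46, −0.14 and −1.02 and at −0.14, 0.79 and −0.94. The cytokinin gene RR16 was at 0.00, 0.20 and 0.74, and the heat shock gene AT1G53540 at 0.00, 0.00 and 0.22. The photosynthesis genes LHCB4.1 and RCA were at 0.04, −0.01 and −0.31 and at −0.12, 0.07 and −0.02, and the clock gene GI at −0.16, −0.33 and −0.59. The glucosinolate genes BCAT4, AT2G31790 and UGT74B1 were at −0.04, −0.30 and −1.11, at −0.01, −0.39 and −0.71, and at −0.01, −0.20 and −0.63. AT3G10040 was the single named member of the 11 hypoxia genes. Of the 30 lists, 10 had 0 named members.

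As a check for tissue other than shoot, 2 of the 19 root markers had a named probe set, EXPA7 and EXPA18. Their values were at most 2.96 in all arrays, under the filter of 3.56. The other root markers could not be checked, so root tissue is not excluded. Of the stomatal markers, FMA was at 0.07, −0.38 and −1.17 and SPCH at −0.04, 0.03 and −1.29, while MUTE and the trichome marker TRY had values of at most 2.70. Flower and seed storage markers had 0 named members. The reference genes AT4G34270, AT2G28390 and AT4G26410 were at −0.04, 0.12 and 0.46, at 0.04, 0.12 and 0.31, and at 0.00, 0.00 and 0.08, with a median over both times of 0.16 (camera adjusted p = 0.272) and at 5 h of 0.22 (adjusted p = 0.138).

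The difference of the estradiol effect between 5 h and 3 h, which asks whether the response changed with time, was 1.41 for UGT85A2 (SE 0.24, unadjusted p = 0.00395) and 3.81 for AT4G38950 (SE 0.72, unadjusted p = 0.00555). Neither passed (adjusted p = 1 for each), and both were named for their 5 h values. UGT85A2 differed by 0.47 at 3 h and AT4G38950 by 0.00. Limma called 0 of 14520 probe sets in either direction, with 25 at an unadjusted p under 0.05. This is again less than a share of 0.05, so the lack of calls is no evidence of an equal effect at both times. With the pair as a block, a setting chosen after seeing the data, it called 0 as well (smallest adjusted p = 0.988), with 425 at an unadjusted p under 0.05. The residual spread of this test came from the 5 h arrays, and the single 3 h arrays were assumed to vary like them.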

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

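The tests in this part on control probe sets, on array splits and on the low-oxygen genes were chosen after the results were seen. The planned interaction test covered the genes listed next.

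For these 6 genes both 5 h pairs differed in the direction opposite to the 3 h pair. At 3 h AT1G74640 was at −0.03, LHCB4.1 at 0.04, FMA at 0.07 and AT4G34270 at −0.04. These are small beside the SD of 0.22 over probe sets in that pair, so their sign there carries little weight. PDF1.2 was at 0.72 and UGT73B4 at −1.13 at 3 h, the latter at 0.07 in replicate 2 of 5 h. The interaction value was 1.08 for AT1G74640 (unadjusted p = 0.0321), −1.84 for PDF1.2 (0.221) and 1.92 for UGT73B4 (0.223). It was −0.20 for LHCB4.1 (0.739), −0.85 for FMA (0.703) and 0.33 for AT4G34270 (0.375), and limma gave an adjusted p of 1 for each.

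The 64 control probe sets, not used in any comparison, showed estradiol minus DMSO differences that ranked alike between pairs, with rank correlations of 0.832, 0.808 and 0.918 across probe sets, which are not independent replicates. Among 10000 random sets of 64 other probe sets the highest was 0.714, and the lowest control value of 0.8083 lies above it, so a candidate explanation is that control values were joined to control names in an order set by the size of the difference. The same mix-up in the other probe sets is argued against, since their levels correlated in rank between pairs at 0.9558 or more, where control levels reached at most 0.7516. True differences in the control RNAs stay open, since the spike-in levels kept their order in 2 of the 3 pairs and it was broken in the remaining pair alone. No biological explanation was tested.

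The lower values of low-oxygen response genes with estradiol were weighed against technical explanations. Probe sets near the floor are argued against, since the median DMSO value of the members was 8.33 where the lowest array value was 2.1, and scaling of the arrays is argued against, since the median was −0.97 with 24 members lower after quantile normalization. Oxygen supply or handling of the flasks may account for it and cannot be told apart from estradiol or MYB112, because no label records the oxygen supply; that the list median was below 0 in 3 of 3 pairs restates the pattern and tests nothing. The camera p was 2.10e-18 for the real split and 2.63e-14 at the smallest of the other splits (1 of 10 as small), while the list medians of 2 other splits, −1.26 and 1.34, were larger in size than the real −1.05, and 10 splits are too few for a share under 0.05. Those 2 part 1 pair each, and among the 4 splits that part all pairs the smallest other p was 9.16e-08 and the lowest other median −0.51.

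For the probe set past the threshold over both times, 1 of 10 splits of the 6 arrays gave as many calls (real 1, highest other 0). These splits are too few for a share under 0.05. For the lists fixed beforehand the real count was 0 (highest other 3), so that 10 of 10 splits gave as many by construction, which tests nothing. Splits that leave pairs together had up to 3073 probe sets at an unadjusted p under 0.05, which points to the pair structure of the arrays. Among the 4 splits that part all pairs, the real split had 276 and the highest other 55.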

How the results depend on the processing

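Leaving out whole pairs, the block in the interaction test, combining the block with an estimated correlation, and all settings for the low-oxygen list were chosen after seeing the data. The 1 rise at 5 h became 0 with the pair as a block, without a filter, without the eBayes trend, with quantile normalization, with arrays centred on the median and in the 4-group fit, and was 0 to 1 without single arrays (0 without either estradiol array of 5 h). The 1 rise over both times became 0 with the block, without a filter, without the trend, with quantile normalization and in the blocked fit without each pair, and was 0 to 1 without single arrays (0 without any 5 h array). The difference of the induced probe set over both times stayed between 9.12 and 10.10 under the alternatives computed for it. The block left fewer degrees of freedom and the missing filter added probe sets, but whether these or other causes account for the lost calls was not tested. Falls stayed at 0, as did interaction calls, under all alternatives run with limma. At 3 h the counts were 12 higher and 34 lower with the 60th percentile filter, which tests fewer probe sets, 174 and 300 at 1.5-fold, and 10 and 25 at 3-fold. In all pairs they were 17 and 23 at 1.5-fold (12 with mixed signs) and 3 and 6 at 3-fold. Without single arrays, which leaves 2 pairs, they were 10 to 33 higher and 18 to 33 lower: 33 and 33 without the 3 h pair, 10 and 26 without replicate 1 of 5 h, 14 and 18 without replicate 2. The low-oxygen list lost its call at 5 h with an estimated correlation (adjusted p = 0.933), with fry (0.998) and with the block and an estimated correlation (0.915), and over both times with the same settings (0.992, 0.975 and 0.996). Over both times with the block, the estimated correlation was 0.34 among the 19 members that were not 2-fold lower in all pairs. The preset of 0.01 thus assumes less correlation than was estimated there. How much of the loss this accounts for was not tested. Of 702 alternatives for named genes, 688 neither changed sign nor crossed the threshold, 7 lost the threshold (all of them the induced probe set) and 7 changed sign. Alternatives without an adjusted p, such as those at 3 h, were counted as not crossing it. Genes named for moving the same way in the pairs could not change sign when a pair was left out. The count of 688 is therefore no evidence of stability. The genes that changed sign ranged without whole pairs from −0.325 to 0.025 for UGT78D2, −0.255 to 0.09 for AT1G06000, −0.54 to 0.325 for GH3.3, −0.16 to 0.015 for LHCB4.1 and −0.07 to 0.025 for RCA. Without either 5 h pair the range was −0.855 to 0.835 for GSTU25 and −0.53 to 0.19 for UGT73B4. These genes were under the filter without the 3 h pair, where their mean differences were 1.53 and 0.79. The cause of the sign changes was not tested. Alternatives for 5 h against 3 h and for the MYB112 level were not run, and signal over background could not be read from these values.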

Other observations

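The family lists, the low-oxygen tests and the genes PDF1.2b, PDF1.4, XTH33 and UGT72E1 in this part were chosen after the values were seen. None of the list tests here was planned.

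Among 31 added lists, camera called the PDF family at 5 h besides the low-oxygen genes (5 members, 5 lower, median −0.56, adjusted p = 0.0120). The adjusted p was 0.0165 with the pair as a block and 0.933 with an estimated correlation. The symbol prefix joins plant defensins with peptide deformylases, which are unrelated enzymes. The defensin genes PDF1.2, PDF1.2b and PDF1.4 were at 0.72, −1.31 and −0.93, at 0.46, −1.88 and −3.52, and at 0.35, −0.06 and −1.06 in the 3 pairs. The probe set of PDF1.2b may share probes with related genes by its suffix, and its interaction value of −3.16 did not pass (unadjusted p = 0.121, adjusted p = 1). Over both times the PDF family was not called (median −0.26, adjusted p = 0.142).

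Other groups were not called in either comparison. The 69 chloroplast-encoded genes had a median of −0.04 and a mean of 0.01 over both times (adjusted p = 0.271), and the 26 UGT family genes a median of −0.01 (adjusted p = 0.976), which was 0.01 after quantile normalization. The 6 CML family genes had medians of −0.54 at 3 h and of −0.15 and 0.02 in the 5 h pairs, with 3 of 6 members higher in each of the latter, and −0.21 over both times (adjusted p = 0.271). XTH33, a cell wall enzyme gene, was at −0.06, −0.86 and −1.04, and UGT72E1 at −0.15, −0.88 and −1.10 in the 3 pairs.

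All 6 of the 1-gene probe sets at least 2-fold lower in all 3 pairs were in the low-oxygen list, which holds 25 of 7781 genes measured (exact Fisher test, one-sided, p = 5.76e-16); the list was drawn up knowing their values, so this is no independent evidence, and neither is what follows on its members. Lower values in all 3 pairs were measured for 16 of 25 members (64.0%) and 1281 of all 7781 genes (16.5%). Without those 6, the other 19 had a median of −0.82 (camera p = 2.76e-11, 1.13e-08 with the block, 0.147 with the block and an estimated correlation). A hypothesis is that estradiol-treated shoots may hold lower transcript levels of low-oxygen genes than DMSO shoots. It restates the pattern from which the list was drawn up, so other samples would be needed to test it. The close array medians within pairs argue against scaling of the arrays as the cause of the lower values here. The median of −0.97 after quantile normalization adds little, since that step had little to change. Whether MYB112, estradiol itself or the flasks lie behind the lower values was not tested, since plants without the construct were not analysed here.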
